A study of Mus musculus with 2 samples.

How the data were processed

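Single-cell suspensions of whole pituitary glands from male C57BL/6 mice were measured with droplet-based 3' RNA sequencing, with 10 glands pooled into 1 library at 2 months and 10 glands pooled into 1 library at 20 months, per the labels. The deposited matrices hold raw UMI counts per gene and barcode for all observed barcodes, with no cell calling and no normalisation by the authors. Reads were aligned to the mouse genome build GRCm39 with Cell Ranger 6.0.2, per the submitters' processing notes, while the matrix header names version 4 of that software. Genome positions were not used here. Each file listed 32285 genes, with 2377253 barcodes in the young and 3445643 in the old library.

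Barcodes were kept with at least 500 detected genes, at most 15% of UMIs from mitochondrial genes and a minimum number of UMIs. The minimum was planned at 1000 UMIs, to be raised in steps of 1000 in both libraries while more than 20000 barcodes passed. At 1000 UMIs, 16514 young and 26404 old barcodes passed, so the minimum was 2000, which 10920 and 10268 barcodes passed. All filters left 9210 and 9783 barcodes. Scrublet scores were computed in each library at an expected doublet rate of 0.8% per 1000 barcodes. Its automatic threshold called 0.0% and 0.031%, and, as fixed in advance for that case, the barcodes with the highest scores were removed at the expected rate, 679 (7.37%) young and 766 (7.83%) old ones.

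Both libraries were clustered together without integration, from 3000 variable genes chosen within each library, 40 principal components, 15 neighbours and Leiden clustering at resolution 1. Clusters were named by markers fixed for 21 classes, as the class with the largest mean log2 fold of its markers over the median cluster, with 5 CPM added, and are called by the name of the class followed by "like". A class needed a score of at least 1, a lead of 0.5 over the next class, at least 3 detected markers, a marker among the 20 leading genes by fold over cells outside the class, and no other class with more markers among the 10 leading ones. A cluster was called free RNA when its profile correlated at 0.95 or more with that of barcodes of 10 to 100 UMIs, across genes of at least 20 CPM there. Details of the naming rule, the correlation limit, a cap of 10% on the expected doublet rate and the rounding of principal components to 3 decimals, made so that a repeat gives identical values, were set after the data were seen. The design, gene lists, markers, rule for named genes and first set of alternatives were fixed before the data were examined.

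UMIs were summed per class and library and expressed as CPM, scaled to a fixed total of the UMIs left without 7 hormone and 13 mitochondrial genes. Ratios are old over young, with exact conditional Poisson intervals, for classes with at least 50 cells in each library. Hormones are given as a percent of all UMIs, beside their percent in barcodes of at most 100 UMIs of the same library. Shares of cells have exact Clopper-Pearson intervals, and a share of 0 is given with the upper limit of 3 counts. Named genes had at least 50 UMIs and 50 CPM in the library where they were higher, a ratio of at least 2 and at least 0.5 times the CPM of that library's empty droplets. Ribosomal protein, mitochondrial and haemoglobin genes and unnamed gene models were left out. The 10 highest and 10 lowest were named in the largest class, 6 and 6 in other classes of at least 200 cells per library, and 3 and 3 in smaller ones, ranked with 0.5 UMI added. Genes with a list median are in addition to these.

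Each of 28 gene lists was summarised in a class by the median log2 ratio of its genes with at least 20 UMIs, where at least 5 were measured. Beside it stands the range from the 2.5th to the 97.5th percentile of 10000 random lists of the same size matched on expression in 20 bins, a description of these 2 libraries and not a test between ages. Cells were thinned to 2000 UMIs for shares of cells with a UMI of a gene. No test, p-value or standard error was computed from cells, since cells of 1 library are not replicates.

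On simulated data, made by changing 100 genes by 2-fold and 100 by 4-fold in each of 2 classes, all 100 genes at each fold had the right direction. The intervals held the fold for 96.0% and 93.0% of genes in somatotroph-like and for 95.0% and 91.0% in corticotroph-like cells, and 20 of 20 named genes were changed ones. The simulated sums were drawn as Poisson counts, which is what the intervals assume, without cells, free RNA, doublets or clustering. They check the calculation only, and not how far the intervals hold in these libraries. Alternatives covered the UMI, gene and mitochondrial limits, doublets, clustering, totals, free RNA, cluster weights and single cells. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.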

Results

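Whole pituitary glands of male C57BL/6 mice, an inbred laboratory strain, were profiled by droplet-based single-cell RNA sequencing at a young age of 2 months and an old age of 20 months. Glands of 10 mice were combined into 1 library per age. The comparison between the libraries addresses how gene expression in each pituitary cell type differs with age. The young library held 154510099 unique molecular identifiers (UMIs, each counting 1 captured transcript) and the old library 138427393. With 1 library per age, no difference could be tested, and each value has no replicate check. Intervals are 95% intervals that cover counting error only, not differences between mice, pools or preparations. Genes are named by the symbols in the files.

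The libraries differed in how UMIs were spread over small barcodes. The young library held 61147 barcodes of 500 to 999 UMIs with 27.7% of its UMIs, against 21765 barcodes with 12.0% of UMIs in the old library, and what these barcodes hold was not tested. Barcodes of at most 100 UMIs, taken as empty droplets, held 4237840 UMIs in the young and 26933036 in the old library. These counts do not compare the amount of free RNA between the libraries. Young barcodes fell from 545 UMIs at rank 76342 to 22 at rank 80132, so the young set lies below the group of 500 to 999 UMIs. Barcodes of 500 to 900 UMIs held 40596018 young and 11577567 old UMIs, and whether they are empty droplets was not tested. After filtering and doublet removal, 8531 young and 9017 old barcodes were kept, with medians of 6317 and 3157 UMIs. A single cluster of kept barcodes matched the profile of empty droplets (r = 0.999 across genes, which are not independent replicates), and the other clusters reached at most 0.904. It held 1 young and 5546 old barcodes, 61.5% (60.5 to 62.5) of those kept in the old library, and is called the free RNA cluster here. The match was made to barcodes below the young group of 500 to 999 UMIs, so free RNA in young barcodes may have been missed. A cluster found almost wholly in 1 library may reflect that library rather than a kind of cell, and shares are therefore given both outside it and over all kept barcodes. Outside it, 8530 young and 3471 old barcodes remained, with medians of 6317.5 and 5848 UMIs.

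**Figure D1:**
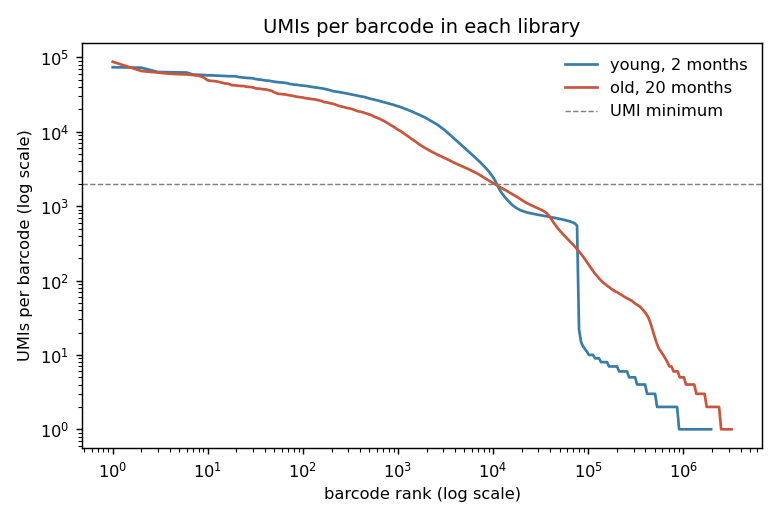
UMIs per barcode (vertical log axis) against barcode rank (horizontal log axis) in the young (blue) and old (red) library, with the minimum of 2000 UMIs dashed. The young curve has a shelf of 61147 barcodes at 500 to 999 UMIs, while 10920 young and 10268 old barcodes lie above the minimum.

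Outside the free RNA cluster, growth hormone-producing somatotroph-like, corticotroph-like and stem cell-like cells took smaller shares of the old library. Melanotroph-like cells of the intermediate lobe, pituicyte-like glia of the posterior lobe, endothelial cell-like cells and every named immune class took larger ones. Somatotroph-like cells made up 47.2% (46.2 to 48.3) of young and 32.8% (31.3 to 34.4) of old barcodes, a ratio of 0.695 (0.650 to 0.742). Corticotroph-like cells made up 14.7% and 8.79%, a ratio of 0.600 (0.527 to 0.680), and stem cell-like cells 11.4% and 8.07%, a ratio of 0.706 (0.616 to 0.807). Melanotroph-like cells were 44 of the young and 151 of the old barcodes, 0.516% (0.375 to 0.692) and 4.35% (3.70 to 5.08), a ratio of 8.43 (5.99 to 12.1). The ratio was 4.06 (2.85 to 5.85) for pituicyte-like cells and 2.26 (1.64 to 3.10) for endothelial cell-like cells. With a minimum of 500 UMIs and 300 genes, however, the pituicyte-like ratio was 1.11, with 172 young and 137 old cells, and the melanotroph-like ratio 5.22. That setting left 17649 young and 15263 old barcodes unnamed, and they make up most of its total outside free RNA in both libraries. Oligodendrocyte-like cells numbered 38 in the old library and 0 of 8530 in the young one, which allows a share of up to 0.0352% by a floor of 3 counts and 0.0432% by the exact interval.

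Lactotroph-like cells, the prolactin producers, made up 4.14% (3.73 to 4.58) of young and 7.58% (6.72 to 8.51) of old barcodes outside free RNA, a ratio of 1.83 (1.55 to 2.15). Macrophage-like cells were at a ratio of 1.35 (1.20 to 1.53), T or NK cell-like cells at 2.83 (2.25 to 3.55), B cell-like cells at 1.66 (1.25 to 2.21) and neutrophil-like cells at 6.49 (4.04 to 10.7). Named immune classes together were 12.3% of young and 21.1% of old barcodes. Over all kept barcodes, the ratio of the lactotroph-like class was 0.705, of the macrophage-like class 0.521, of the B cell-like class 0.641 and of the endothelial cell-like class 0.868, so these directions rest on the total chosen. The neutrophil-like ratio was 2.72 without doublet removal, 3.04 at a clustering resolution of 0.5 and 3.70 without rounding of principal components. The class held 140 young and 151 old, 119 and 147, and 79 and 119 barcodes in these settings, against 25 and 66. They therefore describe a wider class and do not show how stable the share of the smaller one is. With a minimum set in the manner of Cell Ranger (4169.5 young and 2879 old UMIs), the neutrophil-like ratio was 18.8 and the B cell-like ratio 6.95. The young minimum lay above the third quartile of UMIs in young B cell-like (3220.8) and neutrophil-like (3662) cells. It left 21 and 7 of these, against 71 and 64 in the old library, so both ratios rest on the unequal minimum. With each library clustered alone, the endothelial cell-like ratio was 3.41, from 83 young and 116 old cells. The fibroblast-like class held 28 young and 0 old cells there. The old endothelial cell-like class may thus hold fibroblast-like cells, and the ratio does not compare like classes. With a minimum of 500 UMIs and 300 genes, the ratio outside free RNA was 0.718 for macrophage-like, 0.992 for endothelial cell-like, 1.06 for B cell-like, 1.51 for T or NK cell-like and 1.48 for neutrophil-like cells, 0.373 for somatotroph-like, 0.377 for corticotroph-like and 0.361 for stem cell-like cells and 0.871 for the immune classes together, and over all kept barcodes it was 0.491 for pituicyte-like cells. Those of the somatotroph-like (0.268), corticotroph-like (0.231), stem cell-like (0.272), melanotroph-like (3.25) and pituicyte-like (1.56) classes had the same direction under both totals. Among the 5739 young and 1894 old endocrine cells, a total that leaves free RNA aside, the ratio was 2.26 (1.92 to 2.66) for lactotroph-like, 10.4 (7.39 to 14.9) for melanotroph-like, 1.70 (1.10 to 2.60) for gonadotroph-like, 0.857 (0.802 to 0.915) for somatotroph-like and 0.739 (0.650 to 0.839) for corticotroph-like cells. The melanotroph-like ratio among endocrine cells was 6.12 with a mitochondrial limit of 25%, and the gonadotroph-like ratio was 1.23 with that limit, 3.10 with a limit of 10% and 2.74 with a minimum of 500 UMIs and 300 genes. These settings also changed the share of barcodes removed as doublets. The gonadotroph-like class held 12 young and 12 old cells with the limit of 10%, against 64 and 36 with that of 15%. With the minimum of 500 UMIs it held 17 and 14, and the endocrine total lacked a lactotroph-like class. With each library clustered alone, no old corticotroph-like or gonadotroph-like class was named, and the somatotroph-like ratio among endocrine cells was 1.06. The young endocrine total there held 1268 corticotroph-like and 64 gonadotroph-like cells and the old total none, so 1.06 is not a measured turn.

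Clusters left out of every class by naming thresholds set after the data were seen held 404 young and 277 old barcodes, 4.74% and 7.98% of those outside free RNA. Of these, 310 young and 196 old barcodes lay in a cluster led by Gh, and 94 and 81 lay in a cluster led by Plac8 and Lyz2. The nuclear RNA Malat1 took a median of 0.098% of UMIs in the young and 0.30% in the old unnamed barcodes, against 2.88% and 3.97% in all barcodes outside free RNA. Proliferating cell-like barcodes numbered 147 in the young and 1 in the old library, and 60.5% of the young ones had under 0.5% of UMIs from Malat1.

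**Figure D2:**
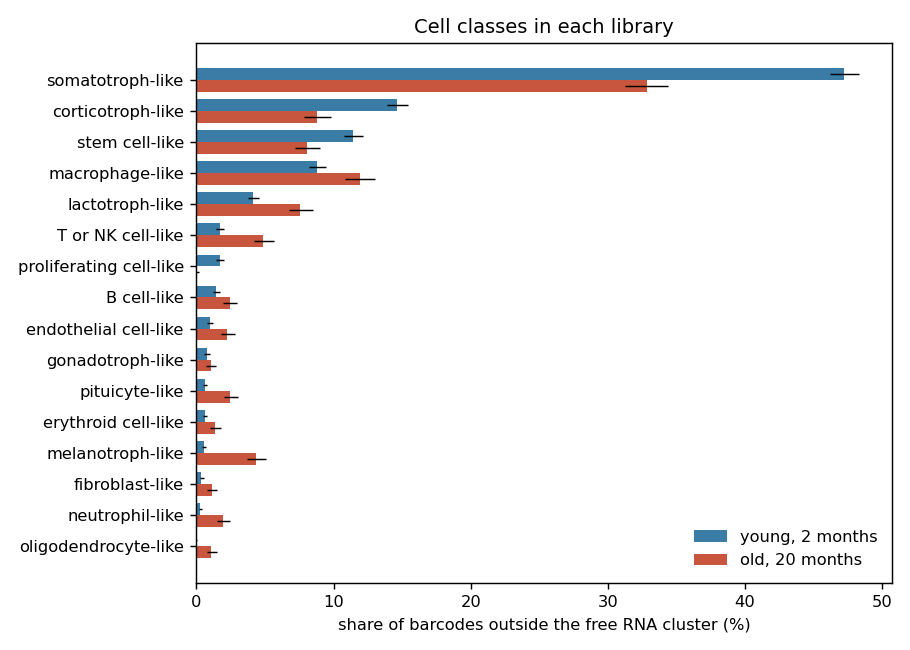
Share of each named class among barcodes outside the free RNA cluster (horizontal axis, percent) in the young (blue) and old (red) library, with exact binomial 95% intervals for counting error. Somatotroph-like barcodes are at 47.2% and 32.8%, and melanotroph-like barcodes at 0.516% and 4.35%.

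Of the hormone transcripts, prolactin (Prl) was lower in lactotroph-like and growth hormone (Gh) in somatotroph-like cells of the old library, and pro-opiomelanocortin (Pomc), the precursor of corticotropin, was higher in corticotroph-like but not in melanotroph-like cells. Prl took 12.6% of all UMIs of young and 5.32% of old lactotroph-like cells, a ratio of 0.423 (0.420 to 0.425), and 0.509% and 0.759% of UMIs in empty droplets. Gh took 43.6% of UMIs of young and 32.6% of old somatotroph-like cells, a ratio of 0.747 (0.746 to 0.748). Empty droplets held close to as much Gh, 40.5% and 28.9%, and T or NK cell-like cells, which do not make it, 7.42% and 4.85%. Pomc took 3.60% of UMIs of young and 8.91% of old corticotroph-like cells, a ratio of 2.48 (2.47 to 2.49), and was at 1.14% and 4.51% in empty droplets. In melanotroph-like cells Pomc was lower, at 9.09% and 8.20%, a ratio of 0.902 (0.889 to 0.915) and a direction that reversed with a minimum of 800 genes. In the gonadotroph-like class of 64 young and 36 old cells, the gonadotropin subunit Fshb was at 0.350% (0.337 to 0.363) and 0.357% (0.341 to 0.375), a ratio of 1.02 (0.963 to 1.09). In the same class the shared subunit Cga was at 7.70% and 8.15%, a direction that reversed in other settings. The luteinising hormone subunit Lhb was at 0.0145% and 0.0376%, and the thyrotropin subunit Tshb at 0.440% and 0.0112%, the old value being below the 0.023% of old empty droplets. The cluster of this class scored second as thyrotroph, at 4.44 against 5.76 as gonadotroph, with Tshb among its 10 leading genes, so that thyrotrophs were not separated from it. These intervals are narrow because the sums are large.

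Somatotroph-like cells, 4028 young and 1139 old, showed the largest class-wide contrast for Ccnd1, the gene of the cell cycle regulator cyclin D1. It stood at 200 CPM (UMIs scaled to a fixed total, without hormones and mitochondrial genes) in the young and 13.4 in the old library, 14.9-fold lower (12.2 to 18.3). Other genes lower in the old library were the chemokine gene Cxcl1 (6.58-fold, 5.08 to 8.67), Arhgap36 (6.28-fold, 5.07 to 7.86), the collagen chaperone gene Serpinh1 (3.40-fold, 2.96 to 3.93), the transcription factor gene Sox11 (3.17-fold), Hist1h1c (2.92-fold), the inositol transporter gene Slc5a3 (2.73-fold), the imprinted gene Ndn (2.65-fold), Ifitm2 (2.57-fold) and Rbbp8 (2.35-fold). Higher in the old library were Penk, the proenkephalin gene, at 8.61 and 76.4 CPM (8.87-fold, 7.61 to 10.4), the noncoding RNA gene Snhg11 (6.12-fold, 5.56 to 6.74), Ahnak (3.65-fold), Anxa4 (3.26-fold), Arap2 (3.07-fold), Greb1 (2.65-fold), Rasa2 (2.62-fold), the glutamate receptor gene Grik2 (2.51-fold), the granule protein gene Chga (2.47-fold, 2.33 to 2.62) and the activity-regulated gene Arc (2.32-fold, 2.23 to 2.42). In empty droplets of the young and old library, Ccnd1 was at 123 and 31.0 CPM, Penk at 4.15 and 44.2, Snhg11 at 12.9 and 80.4 and Chga at 202 and 510, and the last 2 were leading genes of the melanotroph-like cluster. As a mean over cells, the log2 ratio of Cxcl1 was −2.05 instead of −2.71.

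Of 14 p53 target genes measured in somatotroph-like cells, 2 were higher in the old library, and the list's median log2 ratio of −0.46 lay below the range of matched random lists (−0.19 to 0.21). Among them were Cdkn1a at 270 and 175 CPM, Gadd45a at 138 and 76.7 and Phlda3 at 33.7 and 14.8. Genes of secretory granules and prohormone processing had a median of 0.35, with 10 of 14 higher, among them the convertase genes Pcsk1 at 59.3 and 113 CPM and Pcsk2 at 23.1 and 52.7, while Pcsk1n was at 2296 and 1411. The list's median was larger in classes that do not make such granules, at 2.24 in B cell-like, 0.78 in T or NK cell-like, 1.19 in macrophage-like, 1.42 in stem cell-like and 1.83 in pituicyte-like cells, and Pcsk2 and Chga were leading genes of the melanotroph-like cluster, whose share was higher in the old library. Pituitary transcription factor genes had a median of 0.48 with 9 of 12 higher, Pou1f1 at 308 and 404 CPM among them. The median was −0.19 for nuclear genes of the respiratory chain and −0.22 for mitochondrially encoded genes, both below the range of random lists. With all UMIs as the total, which shifts every gene of the class and the random lists alike by 0.26, they were 0.08 and 0.04 and still below that range. Interferon response genes had a median of 0.39 and genes of senescence and its secretory phenotype one of 0.43, which turned to −0.43 when free RNA was subtracted. MHC class II (1.86), inflammatory mediator (0.89) and complement (0.67) genes were higher too, and so were markers of immune (1.27) and endothelial (1.85) cells, which somatotrophs lack. After subtraction of the free RNA profile of 500 to 900 UMIs, the medians were −6.62 for MHC class II, −2.50 for inflammatory mediator, −0.56 for complement and −5.94 for immune marker genes, and with the planned profile of at most 100 UMIs they were 0.97, 0.10, 0.86 and 1.90. The value of 1.90 is that of a gene with no UMIs left in either library. It is set by the class totals and the added 0.5 UMI, and measures no remaining difference. Subtraction set sums below 0 to 0, so the size of large negative medians may rest on that step too, here and in other classes. The proportions of the class's clusters differed between the libraries: cluster 1 held 1294 young and 99 old cells, cluster 2 1100 and 381, cluster 3 834 and 232 and cluster 11 800 and 427. With clusters weighted as in the young library, the log2 ratio of Gh was −0.18 instead of −0.42 and that of Ccnd1 −4.41 instead of −3.89.

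Corticotroph-like cells, 1250 young and 305 old, had lower Ccnd1 as well, at 188 and 16.8 CPM (11.2-fold, 8.36 to 15.3), and lower troponin genes Tnni3 (8.64-fold, 6.16 to 12.5) and Tnnt1 (6.41-fold, 5.61 to 7.36), the latter a leading gene of their clusters. Fosl2, Doc2g and Maff were 3.57-fold, 3.57-fold and 3.54-fold lower. Immediate early genes, which respond within minutes to stimulation or to dissociation of a tissue, were lower together: 0 of 18 were higher in the old library, with a median of −0.62 against a random range of −0.12 to 0.19. Fos stood at 11409 and 7642 CPM, Junb at 9586 and 5013 and Nr4a1 at 1003 and 424. In contrast, 18 of 20 genes of the unfolded protein response were higher (median 0.44, random range −0.10 to 0.22), among them the chaperone gene Hspa5 at 866 and 1188 CPM and Calr at 310 and 464. Of 14 secretory granule genes 11 were higher (median 0.53), with Pcsk1 at 96.7 and 237 CPM and Chgb at 552 and 1126, a median that was also below those of the classes that do not make granules. Imprinted growth genes had a median of 0.47 with 13 of 18 higher, such as Meg3 at 4870 and 8457 CPM, but the median was 0.13, within the random range, without doublet removal. Among hypothalamic and steroid receptor genes, 8 of 11 were higher (median 0.70), while the receptor genes for the class's own hypothalamic hormone and for glucocorticoids, Crhr1 and Nr3c1, were at 139 and 114 and at 508 and 409 CPM; this median was 0.06 without doublet removal. Higher single genes were Snhg11 (8.49-fold, 7.42 to 9.74), Rgs4 (8.46-fold, 6.15 to 11.8), Nrxn3 (4.62-fold), Rab3c (3.48-fold), Kcnh7 (3.19-fold) and Dmd (2.88-fold). Rgs4 was found in 22 young and 40 old cells, with 30.8% of its young and 29.4% of its old UMIs in 1 cell. Immune markers had a median of 1.51 in this class, and of 1.46 and −3.28 after subtraction of the planned profile and of that of 500 to 900 UMIs. The value of 1.46 is that of a gene with no UMIs left in either library, and measures no remaining difference.

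Lactotroph-like cells, 353 young and 263 old, had lower cyclin D genes, Ccnd1 at 221 and 27.0 CPM (8.17-fold, 6.02 to 11.3) and Ccnd2 at 842 and 215 (3.93-fold, 3.51 to 4.41). Gng3, Eno3, Basp1 and Marcks were 3.20-fold, 3.20-fold, 3.03-fold and 2.79-fold lower. Of 77 ribosomal protein genes 1 was higher in the old library (median −0.46, random range −0.35 to −0.07), and of 76 nuclear respiratory chain genes 5 were higher (median −0.44, random range −0.21 to 0.11). Higher in the old library were Snhg11 (12.0-fold, 9.33 to 15.8), the stress cytokine gene Gdf15 (10.5-fold, 6.28 to 18.6), Gucy2f (9.61-fold, 5.34 to 18.8), the immediate early gene Egr4 (9.09-fold, 5.50 to 15.9), Phldb2 (6.83-fold) and the MHC class I gene H2-Q4 at 64.0 and 300 CPM (4.68-fold, 3.90 to 5.65). MHC class I genes had a median of 0.71 with 9 of 10 higher, and genes of the stem cell and Notch, Wnt and Hippo list a median of 1.11 with 7 of 8 higher. Gdf15 rested on few cells: 1 cell held 37.1% of its 124 old UMIs, and the log2 ratio was 1.66 instead of 3.35 as a mean over cells. That of Egr4 lay at 1.89 instead of 3.15 without doublet removal. Immune markers had a median of 0.83, and of 0.57 and −3.98 after both subtractions. The value of 0.57 is that of a gene with no UMIs left in either library, and measures no remaining difference. Old lactotroph-like cells were shallower than young ones, with medians of 4981 and 8461 UMIs, and differed in Malat1, at medians of 8.04% and 3.37% of UMIs, and in mitochondrial UMIs, at 7.41% and 5.84%.

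Stem cell-like cells, 975 young and 280 old, had lower collagen and matrix genes and a higher cyclin D2 gene in the old library. Of 11 matrix genes 2 were higher (median −0.58, random range −0.20 to 0.30), with Col4a1 at 98.2 and 52.7 CPM, Fbn1 at 28.1 and 14.6 and Sparc 2.50-fold lower (1.88 to 3.40). Interferon response genes had a median of −0.37 with 5 of 19 higher, with Ifitm3 at 1983 and 1370 CPM. The stem cell and Notch, Wnt and Hippo list had a median of −0.26, with Hes1 at 591 and 390 CPM and Sox2 at 670 and 605, and a median of −0.18, within the random range, after subtraction of free RNA. Genes of lipid and cholesterol synthesis had a median of −0.21. Ccnd2 stood at 124 and 387 CPM (3.11-fold higher, 2.83 to 3.41; log2 ratio 0.91 instead of 1.64 without doublet removal), and Ccnd1 at 257 and 348 CPM. Tac1, the substance P precursor gene, was 4.24-fold (3.51 to 5.13), the glutathione transferase gene Gsta3 3.58-fold (2.96 to 4.32), Elobl 8.08-fold (6.12 to 10.8) and Snhg11 37.3-fold (22.8 to 65.3) higher, the last at a log2 ratio of 4.19 instead of 5.18 without doublet removal. Elobl was found in 16 young and 14 old cells, with 29.6% of its young and 42.0% of its old UMIs in 1 cell. Lower were Hist3h2ba (3.05-fold), Mapk13 (2.61-fold), Gpha2, which encodes a glycoprotein hormone subunit (2.38-fold, 2.07 to 2.74), Npnt (2.31-fold) and Marcks (2.27-fold). Bpifa1 counted 2 young and 1547 old UMIs, a ratio with an interval of 653 to 19513, but 1 old cell held 98.6% of them, and without it the log2 ratio was 5.56 instead of 10.88. Genes of other cells were also higher, with medians of 1.42 for secretory granule genes, 3.06 for erythroid and 1.06 for immune markers, the last at 1.70 and −4.77 after both subtractions. The first was 0.44 without doublet removal and the erythroid one 0.38 with a minimum of 800 genes. The immune value of 1.70 is that of a gene with no UMIs left in either library, and measures no remaining difference.

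**Figure D3:**
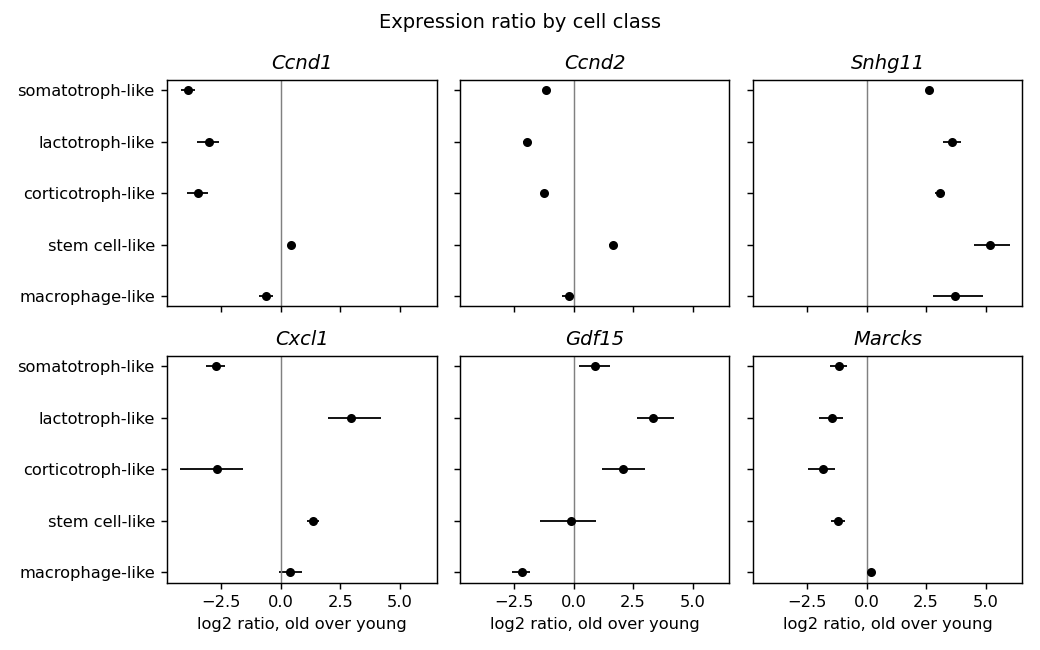
Log2 ratio of old over young CPM (horizontal axis) for 6 genes in 5 classes, 1 panel per gene, with points for the ratio and bars for 95% intervals of counting error. Ccnd1 lies at −3.89, −3.02 and −3.47 in somatotroph-like, lactotroph-like and corticotroph-like cells and at 0.44 in stem cell-like cells.

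Macrophage-like cells, 750 young and 413 old, had lower interferon response, heat shock and cell cycle genes in the old library. Of 19 interferon response genes 3 were higher (median −0.77, random range −0.03 to 0.36). Ifit1 stood at 77.1 and 16.2 CPM (4.76-fold lower, 3.34 to 6.97), Isg15 at 266 and 125, and the interferon gene Ifnb1, at 72.6 and 13.9 CPM, was 5.22-fold lower (3.57 to 7.90). Ifnb1 was found in 41 young and 6 old cells, with 43.3% of its 30 old UMIs in 1 cell. Rsad2 was 4.24-fold lower, the chemokine gene Cxcl10 3.37-fold (3.12 to 3.65), Gdf15 4.56-fold (3.53 to 5.96) and Ehd1 3.84-fold. Inflammatory mediator genes had a median of −0.22 with 6 of 18 higher, Tnf at 286 and 142 CPM and Ccl4 at 7440 and 3782 among the lower ones and Il1b at 1660 and 1476. Heat shock protein genes had a median of −0.61 with 1 of 13 higher, such as Hspa1a at 5892 and 3041 CPM. None of 14 cell cycle genes was higher, with a median of −1.31 that was −2.00 with a mitochondrial limit of 10% and −0.45 with at least 0.5% of UMIs from Malat1, and with Mki67 at 25.9 and 1.85 CPM. MHC class II genes were all higher, 7 of 7, with a median of 0.46 and Cd74 at 12021 and 15106 CPM. Higher single genes were H2-M2 at 21.4 and 126 CPM (5.87-fold, 4.54 to 7.67), Ccdc152 (5.40-fold), the collagenase gene Mmp13 (5.02-fold, 3.75 to 6.80) and Lrrc3 (3.09-fold). The granule genes Chga (4.01-fold) and Scg2 (3.97-fold), which belong to endocrine cells, were also higher, with 47.5% and 34.3% of their old UMIs in 1 cell, and endothelial markers had a median of 2.90, or 2.00 as a mean over cells. The log2 ratio of Scg2 was 1.35 instead of 1.99 with a minimum of 800 genes and 5.10 after subtraction of the profile of 500 to 900 UMIs, and that of Gdf15 −2.92 instead of −2.18 as a mean over cells.

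The remaining classes were small. In endothelial cell-like cells (85 young, 78 old), collagen and matrix genes had a median of −1.34, with Col4a1 at 1354 and 337 CPM and Col4a2 at 794 and 142. Interferon response genes had a median of −0.85 with 1 of 17 higher, the class's own markers one of −0.64, and 18 of 18 immediate early genes were higher (median 0.95). Markers of other cells and several further lists were higher too, with medians of 0.995 for immune markers (7 of 7 higher), 2.00 for MHC class II (6 of 6), 1.45 for inflammatory mediator (6 of 8) and 0.67 for secretory granule genes (8 of 11). Without doublet removal, the medians were −0.60 for matrix, 0.26 for immediate early, 0.89 for MHC class II and 0.02 for secretory granule genes. Aplnr, the apelin receptor gene, was 14.7-fold (7.40 to 33.2), the tight junction gene Cldn5 8.85-fold (4.63 to 18.6) and Mmrn1 6.19-fold lower, and Apod, Gas1 and Sox9 were 18.6-fold, 6.97-fold and 6.48-fold higher. Of young Cldn5 UMIs, 1 cell held 45.3%, and the log2 ratio was −2.06 instead of −3.09 as a mean over cells, where that of Gas1 was 0.39 instead of 2.68. With a mitochondrial limit of 10% and without doublet removal, the Apod direction turned to −2.03 and −1.83 on the log2 scale, Sox9 was at 0.89 and 0.71 instead of 2.61, and 4 of the 6 genes kept a ratio of at least 2-fold. The first setting also removed fewer young doublets, 3.10% instead of 7.37%, so it is not independent of the second. In both settings no fibroblast-like class was named, and the endothelial cell-like class was larger. It held 124 young and 114 old cells in the first and 144 and 120 in the second. Apod was a leading gene of the fibroblast-like cluster. These values, and the medians without doublet removal, may therefore include fibroblast-like cells. Without its top cell Sox9 was at 4.38. In pituicyte-like cells (52 young, 86 old), Gem was 7.77-fold lower (4.48 to 14.2), Scg3 8.77-fold higher (3.29 to 33.0), and Syt1 and Dclk1 counted 1 young UMI each against 69 and 57, with ratios between 5.53 and 1277 and between 4.54 and 1058. Without doublet removal, the log2 ratio was 1.64 instead of 2.97 for Scg3, 1.15 instead of 4.42 for Syt1, 2.33 instead of 4.15 for Dclk1 and −2.00 instead of −2.93 for Gem, and after subtraction of free RNA it was 5.83, 5.92 and 5.75 for the first 3. Secretory granule genes, which belong to endocrine cells, had a median of 1.83 with 13 of 13 higher, and MHC class II genes one of 3.01 with 4 of 5 higher, which was −1.02 without doublet removal and −0.96 after subtraction of free RNA. The value of −0.96 is that of a gene with no UMIs left in either library, and measures no turn of direction. Apod and Avp were 20.2-fold and 6.59-fold lower there, with 98.2% and 79.1% of young UMIs in 1 cell, without which the log2 ratios were 0.42 and −0.81, and free RNA was estimated at 13.0% and 23.9% of the class's UMIs. In T or NK cell-like cells (147 young, 169 old), the T cell receptor delta gene Trdc was 4.19-fold (2.55 to 7.10), Klra7 2.77-fold and the granzyme gene Gzma 2.54-fold (2.32 to 2.79) lower. With the class's clusters weighted as in the young library, the log2 ratio of Gzma was −0.08 instead of −1.34 and that of Klra7 −0.64 instead of −1.46. Atxn1 was 10.9-fold higher (4.07 to 41.1), Ttn counted 1 and 55 UMIs with 78.2% of the old ones in 1 cell, and Snhg11 counted 0 and 54, at least 11.2-fold higher against a floor of 3 counts, with an interval that begins at 8.81. Both were leading genes of the melanotroph-like cluster. Without doublet removal, the log2 ratio was 1.90 instead of 3.29 for Atxn1, 2.42 instead of 4.53 for Ttn and 3.32 for Snhg11. In B cell-like cells (124 young, 84 old), the light chain gene Iglc2 was 3.11-fold (2.55 to 3.80), Ifi27l2a 3.12-fold and Rilpl2 2.97-fold lower, with Iglc2 at a log2 ratio of −1.01 instead of −1.63 without doublet removal. Cck, Chga and Mt3 were higher there, with 100%, 96.7% and 92.2% of old UMIs in 1 cell, without which the log2 ratios were −0.089, 0.78 and 2.23.

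Of 212 list medians over 9 classes, hormones aside, 68 lay above and 38 below the range of the random lists. Other lists fixed in advance lay within the range of the random lists in several large classes. Antioxidant genes had medians of −0.11 in somatotroph-like and 0.04 in stem cell-like cells, and chromatin and DNA repair genes 0.08 and 0.01. Autophagy and lysosome genes had a median of −0.16 in stem cell-like cells, within the range, and of −0.21 in somatotroph-like cells, below its lower end of −0.18. In corticotroph-like cells, heat shock genes (−0.27) and p53 targets (−0.29) lay below the range, and cell cycle genes (−0.36) lay within it. Cell cycle genes had a median of −0.40 in somatotroph-like cells, below the lower end of −0.29.

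Cells with a UMI of the proliferation gene Mki67 were rarer in the old library, and those with a UMI of Cdkn1a, the p21 gene, somewhat rarer when all classes were pooled, while the lower share of Top2a, another proliferation gene, at 2000 UMIs per cell rested on the proliferating cell-like cluster. After each cell was thinned to 2000 UMIs, which left out no cell, Mki67 was found in 143 of 8530 young cells, 1.68% (1.41 to 1.97), and in 19 of 3471 old cells, 0.547% (0.330 to 0.854). Top2a was found in 0.903% (0.713 to 1.13) and 0.490% (0.286 to 0.783). Without the proliferating cell-like cluster, the shares were 1.03% (0.821 to 1.27) and 0.519% for Mki67 and 0.441% (0.311 to 0.608) and 0.461% for Top2a, the latter 1.66% and 1.04% without thinning. T or NK cell-like and unnamed cells had higher shares in the old library, with Mki67 in 3 of 147 young and 5 of 169 old T or NK cell-like cells and in 5 of 404 and 7 of 277 unnamed cells, and Top2a in 5 and 6 and in 1 and 4 of these. Cdkn1a was found in 16.4% (15.6 to 17.2) and 13.5% (12.4 to 14.7), shares that also mix classes in different proportions. Its share was 24.3% and 12.8% in corticotroph-like, 19.3% and 13.8% in macrophage-like and 18.0% and 16.0% in somatotroph-like cells, but 17.7% and 25.4% in T or NK cell-like and 18.1% and 23.5% in unnamed cells. Cdkn2a, the p16 gene, was found in 13 young cells, 0.152% (0.0812 to 0.261), and 15 old cells, 0.432% (0.242 to 0.712), while its CPM in somatotroph-like cells was 1.03 and 0.922. Without thinning, the shares were 3.70% and 1.21% for Mki67, 2.27% and 1.07% for Top2a, 34.9% and 27.0% for Cdkn1a and 0.621% and 1.24% for Cdkn2a. As background, the class with the lowest CPM of Cdkn1a held it in 3.85% of young pituicyte-like cells and 4.56% of old lactotroph-like cells, at medians of 6538.5 and 4981 UMIs before thinning. The background classes of the other genes were at 0, namely 0 of 124 and 0 of 84 B cell-like cells for Cdkn2a, with medians of 2873.5 and 3904.5 UMIs. For Mki67 they were 0 of 64 young gonadotroph-like and 0 of 84 old B cell-like cells, and for Top2a the same young class and 0 of 66 neutrophil-like cells. In stem cell-like cells, Cdkn1a was at 2.77% and 3.57%, at or below that background.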

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

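For Ccnd1, the test on the other classes was chosen after the result was seen, as were both tests on the shares of intermediate and posterior lobe cells, while the other tests were written before their results.

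Some genes differed between the libraries in opposite directions, at least 2-fold each way, in classes of at least 200 cells per library, and these differences between classes were not tested. Ccnd2 had a log2 ratio of 1.64 in stem cell-like cells and of −1.23, −1.97 and −1.15 in corticotroph-like, lactotroph-like and somatotroph-like cells. Cxcl1 was at 1.35 in stem cell-like and −2.71 in somatotroph-like cells. Egr4 was at 3.15 in lactotroph-like and −1.26 in corticotroph-like cells, and Gdf15 at 3.35 in lactotroph-like and −2.18 in macrophage-like cells.

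Barcodes of at most 100 UMIs, taken as empty droplets and in no comparison of classes, held several transcripts of immune cells at far higher levels in the old library, a difference that was not tested. Of genes with at least 200 CPM and a 10-fold ratio there, limits set after the data were seen, the immunoglobulin genes Igkc and Igha had old over young ratios of 128.92 and 665.03. Igha counted 2 young and 8453 old UMIs, with an interval of 184 to 5492. The neutrophil genes S100a8 and S100a9 had ratios of 12.08 and 11.21, and the chemokine gene Ccl5 one of 10.46. Some other immune genes did not follow. Cxcl10 was at 72.0 and 62.4 CPM, Ifitm2 at 310 and 288, Rsad2 at 18.5 and 13.6 and Ifnb1 at 6.00 and 1.84 in the young and old barcodes. Others were higher in the old ones, with Gzma at 18.0 and 51.3 CPM, Iglc2 at 8.77 and 29.7 and Ifi27l2a at 66.0 and 104. All these were picked from genes named in a class. Their CPM leave hormone and mitochondrial genes out of the total, unlike the ratios above.

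Ccnd1 was lower in old somatotroph-like, lactotroph-like and corticotroph-like cells. Free RNA as the whole cause was excluded, as far as the profiles used stand for it. The log2 ratio was −3.09 or lower in the 3 classes after the profile of barcodes of 500 to 900 UMIs was subtracted, and what those barcodes hold was not tested. With the planned profile of at most 100 UMIs, all 20, 12 and 12 named genes of these classes kept a ratio of at least 2-fold, Ccnd1 among them. Another mix of clusters was excluded for somatotroph-like and corticotroph-like cells, at −3.47 or lower with clusters weighted as in the young library. Without cells holding a UMI of a cell cycle gene, the log2 ratio was −2.48 or lower in the 3 classes. Cycling young cells were not excluded by this, since a cycling cell with no captured UMI of these genes was kept. A lowering of Ccnd1 in every class was excluded by stem cell-like cells, where the ratio was 0.44 (0.32 to 0.56). It was −0.61 in macrophage-like, −0.76 in endothelial cell-like and −1.79 in pituicyte-like cells, so that lower values were not confined to endocrine classes. An age difference may stand behind the pattern, as an untested hypothesis, and a difference between the preparations or pools that acts on some classes stays open with 1 library per age.

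MHC class II genes, which present antigens in immune cells, were higher in the same 3 classes of the old library. Free RNA is a candidate explanation: after the profile of barcodes of 500 to 900 UMIs was subtracted, the lowest median log2 ratio was −6.62, in somatotroph-like cells, with −3.08 in lactotroph-like and −4.29 in corticotroph-like cells. These values overshoot 0. Sums below 0 were set to 0 before 0.5 UMI was added, so their size may rest on that step. What barcodes of 500 to 900 UMIs hold was not tested. The young profile of these barcodes differed from that of at most 100 UMIs, at 1.22% and 6.57% mitochondrial and 0.382% and 1.61% Malat1 UMIs. With the planned profile of at most 100 UMIs, the medians were 0.97, 0.57 and 1.46. The values of 0.57 and 1.46 are those of a gene with no UMIs left in either library, set by the class totals and the added 0.5 UMI. They do not measure these genes, although 1.46 lay above the random range. Immune cells sharing droplets with endocrine cells cannot be told apart from other sources, since the 5% of old cells with most of these UMIs held 24.14% of them in somatotroph-like, 39.33% in lactotroph-like and 44.56% in corticotroph-like cells, the first of them below and the others above the lower limit set in advance, which had to hold in all 3 classes. An age difference in these cells stays open and was not tested.

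Melanotroph-like, pituicyte-like and oligodendrocyte-like cells together made up a larger share of the old library, 96 young and 275 old cells. The mitochondrial limit as the whole cause was excluded for melanotroph-like cells, since their ratio was 5.12 (4.14 to 6.36) with a limit of 25%. It was 8.43 with the limit of 15%, so a part of the pattern may rest on the limit. Melanotroph-like cells went from 44 to 134 in the young and from 151 to 259 in the old library. That setting also removed 2.675% of young and 8.14% of old barcodes as doublets, so it does not show the limit alone. More intermediate and posterior lobe in the old pool cannot be told apart from other sources, because its test, on whether the lower of the melanotroph-like and pituicyte-like ratios lay above 1 (it was 4.06), only restates the pattern. With a minimum of 500 UMIs and 300 genes, the pituicyte-like ratio was 1.11. A larger intermediate and posterior lobe at the old age was not tested.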

How the results depend on the processing

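The alternatives on Malat1, cluster weights, the free RNA total, the profile of 500 to 900 UMIs, the top cell, rounding, the proliferating cell-like cluster and the unnamed cluster led by Gh were chosen after the data were seen, and the others before. No paired analysis was possible because each age is 1 pooled library with no samples to pair. Doublet removal changed with some limits, since the automatic threshold was used where it called at least 0.5% of barcodes. It removed 3.10% of young barcodes at a mitochondrial limit of 10%, 2.675% of young ones at 25% and 1.06% of old ones at 500 UMIs. The other library lost the expected rate each time, so these alternatives do not show the limit alone. The median ratio set to 1 and all UMIs as the total shift every gene of a class and its random lists alike, so that the side of the random range is fixed there and only the sign can turn. The first lowered log2 ratios by 0.23 in macrophage-like, 0.18 in T or NK cell-like, 0.17 in B cell-like and 0.15 in lactotroph-like cells and the second raised them by 0.26 in somatotroph-like and 0.15 in lactotroph-like cells, with smaller shifts elsewhere. Of the 212 list medians, 206 kept their direction and their side of the random range with weighted clusters and 170 and 166 after the planned and the added subtraction of free RNA. Of the 206, lists of the lactotroph-like (23), stem cell-like (26), endothelial cell-like (25), pituicyte-like (21) and B cell-like (18) classes could not change. Each of these classes is 1 cluster, so weighting leaves its values as they are. The 170 include medians set by genes with no UMIs left in either library, as for MHC class II in corticotroph-like cells. Of 92 named log2 ratios, 88, 75 and 74 stayed within their counting intervals with the median ratio set to 1, with all UMIs as the total and as a mean over cells, and 2 turned direction without the top cell. With each library clustered alone, no old corticotroph-like, gonadotroph-like or fibroblast-like class was named, and with a minimum of 500 UMIs no lactotroph-like class was named, so these have no value there. Endocrine totals there leave these classes out. No fibroblast-like class was named with a mitochondrial limit of 10% or 25%, without doublet removal or at resolution 0.5. The endothelial cell-like class was larger in these settings and may include fibroblast-like cells. The neutrophil-like class was larger without doublet removal, at resolution 0.5 and without rounding of principal components. Its ratios there are those of a wider class. Each age has 1 library, whose depth sets the counting intervals, and the cause was not tested for any value below other than those with all UMIs as the total. Those whose called direction turned are given first under each alternative. A direction counts as called where the counting interval leaves out a ratio of 1 or the list median lies outside the random range, so that other values below may lie on either side, as the T or NK cell-like ratio of 0.667 with a minimum of 500 UMIs and 300 genes does.

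With the free RNA cluster left out of the total, direction turned where the ratio of shares of kept barcodes was 1.66 for B cell-like, 1.38 for gonadotroph-like, 1.83 for lactotroph-like, 1.35 for macrophage-like and 1.72 for named immune classes together. Among values without a called turn, the ratio of shares of kept barcodes was 2.83 for T or NK cell-like, 0.600 for corticotroph-like, 2.26 for endothelial cell-like, 2.22 for erythroid cell-like, 3.09 for fibroblast-like, 8.43 for melanotroph-like, 6.49 for neutrophil-like, 4.06 for pituicyte-like, 0.695 for somatotroph-like, 0.706 for stem cell-like, 0.811 for endocrine classes together and 7.04 for the melanotroph-like, pituicyte-like and oligodendrocyte-like classes together.

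With all UMIs as the total, direction turned where list medians were 0.076 for respiratory chain, 0.040 for mitochondrially encoded, 0.057 for lysosome and 0.087 for lipid synthesis genes in somatotroph-like cells, turns made by that shift alone, since all 4 stayed below their random ranges.

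As a mean over cells, direction turned where list medians were 0.020 for respiratory chain genes in macrophage-like cells, −0.14 for imprinted genes in pituicyte-like cells. With no called direction turned, list medians were 0.39 for antioxidant and 0.48 for lipid synthesis genes in B cell-like cells, 0.49 for complement and 0.068 for ribosomal protein genes in corticotroph-like cells, −0.17 for MHC class I genes in endothelial cell-like cells, −0.29 for p53 target and 0.15 for immediate early genes in lactotroph-like cells, 0.23 for heat shock, 0.029 for antioxidant and −0.55 for collagen and matrix genes in pituicyte-like cells, −0.35 for cell cycle genes in somatotroph-like cells.

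With free RNA subtracted, direction turned where list medians were −0.96 for MHC class II and −0.96 for inflammatory genes in pituicyte-like cells, −0.43 for senescence genes in somatotroph-like cells, −1.45 for MHC class II genes in stem cell-like cells. The values of −0.96 are those of a gene with no UMIs left in either library, so they are not measured turns. Direction also turned where the log2 ratio of the hormone share was −0.032 for Cga in gonadotroph-like cells. Short of a called turn, list medians were 0.71 for antioxidant genes in B cell-like cells, 0.69 for immune marker genes in T or NK cell-like cells, 0.36 for MHC class I, 0.65 for complement and 0.048 for ribosomal protein genes in corticotroph-like cells, −0.21 for p53 target, 0.57 for MHC class II, 0.57 for inflammatory and 0.57 for immune marker genes in lactotroph-like cells, −0.18 for MHC class I, −0.17 for complement and −0.28 for immune marker genes in macrophage-like cells, 0.25 for MHC class I and 0.13 for antioxidant genes in pituicyte-like cells, 0.26 for interferon, 0.14 for MHC class I, 0.97 for MHC class II, 0.10 for inflammatory, −0.22 for mitochondrially encoded, −0.35 for cell cycle and −0.16 for lipid synthesis genes in somatotroph-like cells, 0.25 for MHC class I, 0.30 for inflammatory and −0.18 for stem cell and Notch, Wnt and Hippo genes in stem cell-like cells. The values of 0.57 in lactotroph-like cells are those of a gene with no UMIs left in either library, and measure no remaining difference. The log2 ratio of the hormone share was −0.41 for Gh in somatotroph-like, −1.21 for Prl in lactotroph-like, 1.26 for Pomc in corticotroph-like, −0.20 for Pomc in melanotroph-like and −0.081 for Fshb in gonadotroph-like cells.

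With free RNA subtracted by the profile of 500 to 900 UMIs, direction turned where list medians were −4.29 for MHC class II, −0.93 for inflammatory, −0.22 for complement and −3.28 for immune marker genes in corticotroph-like cells, −3.08 for MHC class II, −0.47 for inflammatory and −3.98 for immune marker genes in lactotroph-like cells, −1.18 for MHC class II and −0.96 for inflammatory genes in pituicyte-like cells, −0.62 for senescence, −6.62 for MHC class II, −2.50 for inflammatory, −0.56 for complement and −5.94 for immune marker genes in somatotroph-like cells, −0.75 for MHC class II, −0.75 for inflammatory, −4.85 for complement and −4.77 for immune marker genes in stem cell-like cells. Sums below 0 were set to 0 before 0.5 UMI was added, so the size of large negative medians may rest on that step. The −0.96 in pituicyte-like cells equals the value given above for a gene with no UMIs left, so it is not taken as a measured turn. Another turn was seen where the log2 ratio of Cga share in gonadotroph-like cells was −0.0065. Without such a turn, list medians were 0.63 for antioxidant genes in B cell-like cells, 0.26 for MHC class I and 0.067 for ribosomal protein genes in corticotroph-like cells, 0.47 for immune marker genes in endothelial cell-like cells, −0.13 for p53 target genes in lactotroph-like cells, −0.15 for MHC class I, −0.17 for complement and −0.27 for immune marker genes in macrophage-like cells, 0.28 for MHC class I, 0.11 for antioxidant and 0.22 for imprinted genes in pituicyte-like cells, 0.15 for interferon, 0.15 for MHC class I, −0.087 for cell cycle and −0.19 for lipid synthesis genes in somatotroph-like cells, 0.15 for unfolded protein response and −0.17 for stem cell and Notch, Wnt and Hippo genes in stem cell-like cells. For other quantities, the log2 ratio of the hormone share was −0.40 for Gh in somatotroph-like, −1.25 for Prl in lactotroph-like, 1.26 for Pomc in corticotroph-like, −0.18 for Pomc in melanotroph-like and −0.056 for Fshb in gonadotroph-like cells.

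With clusters weighted as in the young library, list medians were 0.10 for ribosomal protein genes in corticotroph-like cells, 0.20 for interferon, 0.036 for immediate early, −0.34 for cell cycle and −0.14 for lysosome genes in somatotroph-like cells. The log2 ratio of the hormone share was −0.18 for Gh in somatotroph-like cells.

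With genes of 100 or more UMIs, direction turned where list medians were 0.085 for complement genes in macrophage-like cells, −0.0085 for antioxidant genes in pituicyte-like cells. Among values without a called turn, list medians were −0.40 for ribosomal protein and 0.17 for antioxidant genes in B cell-like cells, 0.34 for receptor genes in corticotroph-like cells, 0.35 for secretory granule, −0.27 for MHC class I and 0.23 for heat shock genes in endothelial cell-like cells, 0.20 for senescence and −0.030 for cell cycle genes in somatotroph-like cells, 0.18 for inflammatory genes in stem cell-like cells.

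Without the top cell of the gene, direction turned where the log2 ratio was −0.089 for Cck in B cell-like and 0.42 for Apod in pituicyte-like cells.

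Thinned to 1000 UMIs, the share of cells with a UMI was 9.79% for Cdkn1a in the young library, 7.55% for Cdkn1a in the old library, 0.0586% for Cdkn2a in the young library, 0.95% for Mki67 in the young library and 0.633% for Top2a in the young library.

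Without thinning, the share of cells with a UMI was 34.9% for Cdkn1a in the young library, 27.0% for Cdkn1a in the old library, 0.621% for Cdkn2a in the young library, 1.24% for Cdkn2a in the old library, 3.70% for Mki67 in the young library, 1.21% for Mki67 in the old library, 2.27% for Top2a in the young library and 1.07% for Top2a in the old library.

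Without the proliferating cell-like cluster, the share of cells with a UMI was 1.03% for Mki67 in the young library and 0.441% for Top2a in the young library.

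With at least 0.5% of UMIs from Malat1, direction turned where the ratio of shares outside free RNA was 0.641 for erythroid cell-like cells. Direction turned too where the ratio of shares of kept barcodes was 1.10 for lactotroph-like cells. It also turned where the log2 ratio of the hormone share was −0.15 for Cga in gonadotroph-like cells. With no called direction turned, the ratio of shares of kept barcodes was 0.937 for B cell-like, 1.55 for T or NK cell-like, 0.331 for corticotroph-like, 1.26 for endothelial cell-like, 0.355 for erythroid cell-like, 0.730 for macrophage-like, 4.73 for melanotroph-like, 0.401 for somatotroph-like, 0.387 for stem cell-like, 0.959 for named immune classes together, 0.465 for endocrine classes together and 4.12 for the melanotroph-like, pituicyte-like and oligodendrocyte-like classes together. For other quantities, list medians were 0.075 for ribosomal protein genes in corticotroph-like cells, −0.15 for p53 target genes in lactotroph-like cells, 0.56 for inflammatory and −0.43 for collagen and matrix genes in pituicyte-like cells. The log2 ratio of the hormone share was −0.38 for Gh in somatotroph-like, −1.18 for Prl in lactotroph-like, 1.29 for Pomc in corticotroph-like, −0.12 for Pomc in melanotroph-like and −0.27 for Fshb in gonadotroph-like cells.

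With the unnamed cluster led by Gh counted as somatotroph-like, the ratio of shares of kept barcodes was 0.291 for somatotroph-like cells.

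With a minimum of 500 UMIs and 300 genes, direction turned where the ratio of shares outside free RNA was 0.992 for endothelial cell-like, 0.397 for erythroid cell-like, 0.752 for fibroblast-like, 0.718 for macrophage-like and 0.871 for named immune classes together. Another turn was seen where the ratio of shares of kept barcodes was 0.654 for neutrophil-like, 0.491 for pituicyte-like and 0.979 for the melanotroph-like, pituicyte-like and oligodendrocyte-like classes together. Short of a called turn, the ratio of shares of kept barcodes was 0.470 for B cell-like, 0.667 for T or NK cell-like, 0.167 for corticotroph-like, 0.439 for endothelial cell-like, 0.176 for erythroid cell-like, 0.332 for fibroblast-like, 0.317 for macrophage-like, 0.165 for somatotroph-like, 0.160 for stem cell-like, 0.385 for named immune classes together and 0.186 for endocrine classes together.

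With a minimum of 800 genes, direction turned where the ratio of shares outside free RNA was 0.737 for erythroid cell-like cells. Direction turned too where the log2 ratio of the hormone share was 0.053 for Pomc in melanotroph-like cells. Without such a turn, the ratio of shares of kept barcodes was 0.307 for erythroid cell-like, 0.315 for somatotroph-like and 0.355 for endocrine classes together. For other quantities, list medians were 0.69 for lipid synthesis genes in B cell-like cells, 0.068 for ribosomal protein genes in corticotroph-like cells, −0.11 for MHC class I and −0.14 for complement genes in macrophage-like cells. The log2 ratio of the hormone share was −0.40 for Gh in somatotroph-like, −1.09 for Prl in lactotroph-like and 1.27 for Pomc in corticotroph-like cells.

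With a Cell Ranger style minimum, direction turned where the ratio of shares of kept barcodes was 3.67 for B cell-like and 1.04 for named immune classes together. This minimum was higher in the young library and left 21 young and 71 old B cell-like cells. Among values without a called turn, the ratio of shares of kept barcodes was 2.23 for T or NK cell-like, 0.320 for corticotroph-like, 1.36 for endothelial cell-like, 0.898 for lactotroph-like, 0.649 for macrophage-like, 5.58 for melanotroph-like, 9.93 for neutrophil-like, 0.352 for somatotroph-like, 0.335 for stem cell-like, 0.429 for endocrine classes together and 4.34 for the melanotroph-like, pituicyte-like and oligodendrocyte-like classes together.

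With a mitochondrial limit of 10%, direction turned where the log2 ratio was −2.03 for Apod in endothelial cell-like cells. It also turned where list medians were −0.016 for heat shock genes in endothelial cell-like cells. With no called direction turned, the ratio of shares of kept barcodes was 0.193 for corticotroph-like, 0.844 for gonadotroph-like, 0.584 for lactotroph-like, 0.452 for macrophage-like, 0.225 for stem cell-like, 0.570 for named immune classes together and 0.272 for endocrine classes together. The gonadotroph-like value rests on 12 cells in each library. For other quantities, list medians were 0.076 for mitochondrially encoded and 0.63 for lipid synthesis genes in B cell-like cells, 0.15 for MHC class II genes in T or NK cell-like cells, 0.080 for ribosomal protein genes in corticotroph-like cells, −0.065 for p53 target genes in lactotroph-like cells, 0.35 for transcription factor, 0.17 for senescence, −0.19 for mitochondrially encoded, −0.12 for cell cycle and −0.10 for lipid synthesis genes in somatotroph-like cells.

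With a mitochondrial limit of 25%, the ratio of shares of kept barcodes was 0.571 for lactotroph-like, 2.09 for melanotroph-like, 0.290 for somatotroph-like, 0.342 for endocrine classes together and 1.96 for the melanotroph-like, pituicyte-like and oligodendrocyte-like classes together.

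Without doublet removal, direction turned where the log2 ratio was −1.83 for Apod in endothelial cell-like cells. Another turn was seen where list medians were −0.062 for heat shock genes in endothelial cell-like cells, −1.02 for MHC class II and −0.17 for inflammatory genes in pituicyte-like cells. Short of a called turn, the ratio of shares of kept barcodes was 0.598 for lactotroph-like and 1.02 for neutrophil-like cells. List medians were 0.21 for antioxidant genes in B cell-like cells, 0.32 for secretory granule, 0.32 for MHC class II and 0.26 for imprinted genes in T or NK cell-like cells, 0.061 for receptor, 0.067 for ribosomal protein and 0.13 for imprinted genes in corticotroph-like cells, 0.022 for secretory granule genes in endothelial cell-like cells, 0.44 for transcription factor, −0.12 for MHC class I, −0.11 for complement and 0.34 for imprinted genes in macrophage-like cells, 0.32 for MHC class I and 0.11 for imprinted genes in pituicyte-like cells, −0.13 for stem cell and Notch, Wnt and Hippo genes in stem cell-like cells. For other quantities, the log2 ratio of the hormone share was −0.42 for Gh in somatotroph-like, −1.0 for Prl in lactotroph-like, 1.42 for Pomc in corticotroph-like, −0.022 for Pomc in melanotroph-like, 0.22 for Cga in gonadotroph-like and 0.20 for Fshb in gonadotroph-like cells.

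At resolution 0.5, the ratio of shares of kept barcodes was 1.17 for neutrophil-like and 0.286 for endocrine classes together.

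At resolution 2, the ratio of shares of kept barcodes was 0.294 for somatotroph-like cells.

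With each library clustered alone, direction turned where the ratio of shares of endocrine cells was 1.06 for somatotroph-like cells. The old total lacked the corticotroph-like and gonadotroph-like classes that the young total held, so this is not a measured turn. Without such a turn, the ratio of shares of kept barcodes was 1.32 for endothelial cell-like, 0.561 for lactotroph-like and 0.242 for endocrine classes together. The first may count old fibroblast-like cells, since no old fibroblast-like class was named. The last lacks the same old endocrine classes.

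With hormone genes left out of clustering, the ratio of shares of kept barcodes was 0.297 for somatotroph-like cells.

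Without rounding of principal components, the ratio of shares of kept barcodes was 1.43 for neutrophil-like cells. The log2 ratio of the hormone share was −0.42 for Gh in somatotroph-like and −1.18 for Prl in lactotroph-like cells.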

Other observations

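The values here describe the libraries further, and no test was run on them.

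Snhg11 was higher in the old library in each of the 8 classes that measured it, with log2 ratios of 2.61 in somatotroph-like, 3.08 in corticotroph-like, 3.58 in lactotroph-like, 5.18 in stem cell-like, 3.69 in macrophage-like and 1.83 in pituicyte-like cells. It counted 0 young UMIs in T or NK cell-like and B cell-like cells against 54 and 44 old ones. Empty droplets of the young and old library held it at 12.9 and 80.4 CPM, and it was a leading gene of the melanotroph-like cluster, with 44 young and 151 old cells. Estimated free RNA took 4.36% of young and 8.15% of old UMIs in somatotroph-like, 10.9% and 17.5% in stem cell-like and 17.5% and 20.4% in macrophage-like cells.

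Immediate early genes had medians of 1.05 in pituicyte-like cells, with 17 of 18 higher in the old library, of 0.63 in B cell-like and of 0.44 in T or NK cell-like cells. Ribosomal protein genes had medians of −0.39 in B cell-like and −0.25 in T or NK cell-like cells. In pituicyte-like cells, collagen and matrix genes had a median of −0.71 and genes of the stem cell and Notch, Wnt and Hippo list one of −0.57, with 1 of 12 higher.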
